A study of Drosophila melanogaster with 107 samples.

How the data were processed

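The series holds 107 libraries of sorted Drosophila brain cells, 64 in a developmental table and 43 in a perturbation table. Cells carrying a red fluorescent reporter were sorted, 1000 per library, from flies reared at 25 °C, and males and females were taken at random per the labels. Adults were 3 to 5 days old. Transcripts with a poly(A) tail were sequenced from their 3' ends by MARS-seq, a bulk form of a barcoded single-cell protocol. Each library's group, stage and replicate were taken from its label, and replicates were not stated to be separate animals or separate sorts.

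The deposited values are a score per gene and library: read counts that the authors normalized between the libraries of a table and rounded to whole numbers. The normalization method is not named, and the 2 tables were scaled separately, so that tests were made only within a table. The submitters' processing notes name bcl2fastq, HISAT 0.1.5 and HOMER without giving each a role. The protocol describes molecular barcodes, and whether the values count molecules or reads is not stated. The genome build is not given in the sources used here, so no coordinates are printed. The tables hold 17050 genes, of which 12562 and 11629 have a value above 0.

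Totals per library were 1343651 to 2068007 in the developmental and 1896123 to 2501051 in the perturbation table. Depth before the normalization could be estimated, from the spacing of the smallest values, in 18 developmental libraries and 16 perturbation libraries, where it was 0.476 to 1.68 and 1.01 to 2.13 megareads. Reads without counted molecules are not independent, so such depths bound counting error only. Within-group correlations of log2 values ranged from 0.856 to 0.939, and astrocyte-like cells had 0.733. No library was identical to another, and the highest correlation between libraries of the different tables was 0.857. Among genes with a total of at least 100 reads over a table, the developmental and perturbation values of 370 and 359 genes equalled those of another gene in every library, which can come from overlapping annotation.

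Genes with at least 10 normalized reads in at least 3 developmental or 2 perturbation libraries were tested, 8320 and 8656 genes, and 7862 genes were tested in both. Values were put on the scale log2(value + 1). Linear models with a mean per group were fitted to each table with limma 3.58.1 (empirical Bayes with a trend in the mean level) in R 4.3.3, with statmod 1.5.0. P-values are two-sided and Benjamini-Hochberg adjusted over the genes of a comparison, with 0.05 as the threshold. The developmental table gave 10 comparisons and a limma F test among the 14 γ neuron stages. The perturbation table gave 18, which were each perturbation against control at 4 stages and over the mean of the 3 pupal stages, and the direct differences between perturbations, with the targeted genes also tested for differences of effect between stages.

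A set of 20 gene lists was fixed before the data were examined: ecdysone response, remodeling regulators, proteasome subunits, cytoplasmic ribosomal proteins, axon guidance and cell adhesion, dpr and DIP surface proteins, cytoskeleton regulators, synaptic vesicle and release, voltage-gated and related channels, neurotransmitter receptors, Kenyon cell identity and learning, glial, hemocyte, fat body and photoreceptor markers, neuroblast and cell cycle, heat shock and dissociation response, TGF-beta and BMP signalling, insulin and TOR signalling, and autophagy and cell death. List symbols were matched to the tables directly or through synonyms of the Release 6 annotation. Lists were tested with camera with a preset correlation of 0.01, and adjusted over 200 tests in the developmental and 360 in the perturbation table. Lists of cuticle and tracheal families and of epithelial markers were added after seeing the data.

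Genes named in the text were chosen by a rule fixed before the data were examined. For each pupal mean and each adult cell type comparison it takes the 10 called genes with the largest increase and the 10 with the largest decrease, and for each stage step 6 and 6. Such genes had a mean of at least 50 in the higher group and no overlap between the libraries of the groups (for pupal means, within at least 2 of the 3 stages and in the same direction in all 3). The rule also takes the 12 smallest p-values of the F test, the 3 targeted genes everywhere, and up to 4 members of each list with at least 3 called members or a called camera test. The genes v, mira, wor, C901 and others named beside a marker list come from that list or were chosen after their values were seen.

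Overlap between perturbations, which share control libraries, was set against 100 simulated sets of unchanged groups and against 36 splits of the controls into parts of 4 libraries. Genes of the larva-to-6 h change were counted in each perturbation with Fisher's exact test, two-sided. The procedure was tested on simulated data in which 100 genes were changed by log2 1 and 100 by log2 2. Alternatives were median-ratio rescaling, limma without trend and with robust variances, no filter, a filter at 50, a pseudocount of 10, the replicate number as a block, only the compared groups, and each library left out in turn. Alternatives added after seeing the data left out the astrocyte-like libraries, the Sox14 RNAi libraries A of the third instar and 0 h, and the cuticle and tracheal families. Random splits of libraries, up to 100 per comparison, gave the calls that chance groupings make. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for figures. No library was left out.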

Results

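The series measured polyadenylated transcripts of sorted Drosophila brain cells by sequencing the 3' ends of transcripts in bulk, with 1000 fluorescent cells per library. The cells were mainly γ neurons of the mushroom body, the brain's center for olfactory learning, whose larval axons and dendrites are pruned in the pupa and grow again. The developmental table held 64 libraries of 17 groups. Of these, 52 were γ neurons at 14 stages, with 3 libraries each at the second instar, the third instar, 3 h and 21 h after puparium formation and 4 at each other stage. The other groups had 4 libraries each of adult αβ neurons (a later-born type of mushroom body neuron), adult neurons outside the mushroom body and adult astrocyte-like cells (a glial type). The perturbation table held 43 libraries of γ neurons at the third instar and at 0, 6 and 12 h, with 2 or 3 libraries per group. Its groups were control animals and animals labelled EcR-DN (a dominant-negative ecdysone receptor), E75 RNAi (against the nuclear receptor gene Eip75B) and Sox14 RNAi (against a transcription factor gene).

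Values were the authors' normalized read counts, rounded to whole numbers. Library totals were 1343651 to 2068007 normalized reads in the developmental table, where 5850 to 8354 genes had at least 1 read. They were 1896123 to 2501051 in the perturbation table, with 6649 to 8542 genes. Fold changes are log2 ratios from limma on log2(value + 1), a scale that understates changes of weakly expressed genes, and are given with the standard error. Levels are means of normalized reads. Genes are called higher or lower, or said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05. Replicates were not stated to come from separate animals, so the p-values measure only the spread between libraries.

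The 3 genes named by the perturbations were followed first along development. EcR, the ecdysone receptor gene, was at 2734 reads at the second instar, 4321 at the third instar, 2164 at 0 h, 260 at 3 h and 229 at 6 h, and returned to 681 at 9 h. It fell from the third instar to 0 h (-1.10 ± 0.28) and from 0 to 6 h (-3.13 ± 0.26), and rose from 6 to 18 h (1.31 ± 0.26). Eip75B rose to 24394 reads at 0 h (0.60 ± 0.19) and fell to 6428 at 6 h (-1.92 ± 0.18). Sox14 was at 3077 reads at the third instar and 5160 at 0 h, a change that did not pass the test (0.75 ± 0.57, adjusted p = 0.539). The libraries of these 2 stages did not overlap, at 2385 to 3674 and 3892 to 5872 reads. The standard error rests on the spread within all 17 groups, some with few Sox14 reads, so a rise is not excluded. Sox14 then fell to 487 reads at 6 h (-3.41 ± 0.52) and to 99.5 at 18 h (-2.29 ± 0.52).

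**Figure D1:**
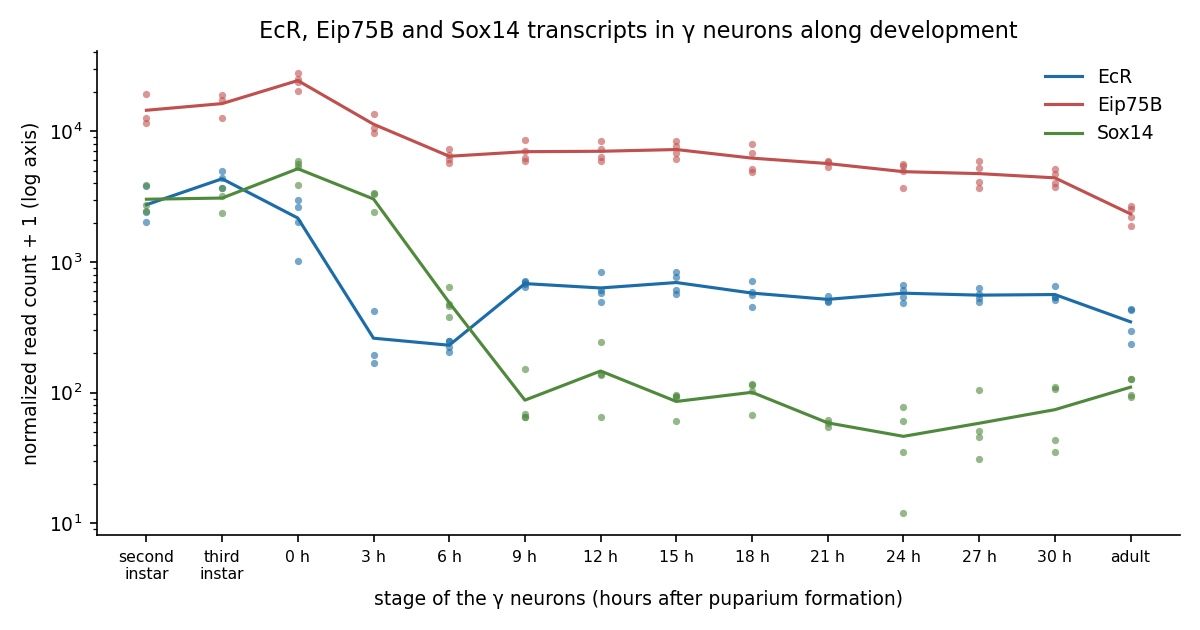
Normalized reads of EcR, Eip75B and Sox14 (log axis, value + 1) in γ neuron libraries at 14 stages (x axis). Points are libraries, lines join stage means, and EcR drops from a mean of 4321 reads at the third instar to 229 at 6 h.

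In all, 3619 of 8320 tested genes differed among the 14 γ neuron stages (limma F test). They included all 25 tested genes of the list Kenyon cell identity and learning, all 32 proteasome subunits, 24 of 26 ecdysone response genes, 30 of 34 neurotransmitter receptors, 21 of 25 synaptic vesicle and release genes and 73 of 84 cytoplasmic ribosomal protein genes. Adjusted over the list alone, these counts were 25, 32, 24, 30, 22 and 73. The 12 genes with the smallest p were noe, blot, CG13298, Pde9, Mef2, CG17816, hdc, chic (the actin-binding protein profilin), Nckx30C, ab, CG9003 and IA-2.

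Few genes separated the third instar from the second, with 3 libraries each. The gene hig, which encodes a protein of the synaptic cleft, was at 6.33 reads at the third instar and 141 at the second (-5.39 ± 0.97), and CG45057 was also lower (-2.79 ± 0.62). In limma, 0 genes were called higher and 13 lower, with 516 at an unadjusted p under 0.05. Members of the Kenyon cell list passed no test singly, and camera called the list higher at adjusted p = 0.038, against adjusted p = 0.484 with an estimated correlation. The count ranged from 5 to 21 when single libraries were left out, and was 0 when only these 6 libraries were fitted.

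At puparium formation, more members of the synaptic, receptor and channel lists fell in γ neurons than rose. Among the genes that fell most from the third instar (3 libraries) to 0 h (4 libraries) were Hr38, an activity-induced nuclear receptor gene (227 to 6.5 reads, -5.99 ± 1.05), the transcription factor gene sr (103 to 4.5 reads) and Ald, which encodes the glycolytic enzyme aldolase (2087 to 86.2 reads, -4.92 ± 0.66). With them fell CG13594 (-5.62 ± 0.77), hoe1 (-5.35 ± 0.93) and CG34357 (-4.84 ± 0.79). The largest increases were in haf (4.68 ± 0.77), CG6231 (4.27 ± 0.82), the neuropeptide receptor gene PK2-R1 (3.78 ± 0.80), CG17075 (3.73 ± 0.45), CG10713 (336 to 3886 reads, 3.56 ± 0.56) and CG12880 (3.49 ± 0.69).

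Of 25 tested synaptic vesicle and release genes, 12 fell and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 1.57e-08, adjusted p = 0.013 with an estimated correlation). Among them were cpx, which encodes complexin (-1.75 ± 0.18), Rbp (-3.03 ± 0.47) and Syn, which encodes synapsin (-1.37 ± 0.22). Of 34 tested neurotransmitter receptor genes, 9 fell and 1 rose (12 and 3 adjusted over the list alone, camera adjusted p = 0.000164, adjusted p = 0.0535 with an estimated correlation). The GABA receptor gene Rdl (-2.42 ± 0.27), nAChRalpha5 (-2.36 ± 0.20) and the dopamine receptor gene Dop1R1 (-1.64 ± 0.19) fell. Of 24 tested voltage-gated and related channel genes, 8 fell and 2 rose (10 and 3 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.24 with an estimated correlation). The sodium channel gene para fell (-1.77 ± 0.26) and KCNQ rose (1.10 ± 0.23). Of 25 tested genes of Kenyon cell identity and learning, 9 fell and 1 rose (14 and 2 adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.0845 with an estimated correlation). They included the transcription factor gene ab (-3.02 ± 0.34) and the adenylyl cyclase gene rut (-1.44 ± 0.28). Of 32 tested proteasome subunits, 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 1.08e-07, adjusted p = 0.0299 with an estimated correlation), with Rpt4 up (0.96 ± 0.29). Autophagy and cell death genes were also higher as a list with Atg3 called (0.85 ± 0.25), at camera adjusted p = 0.00211 and adjusted p = 0.0221 with an estimated correlation. Markers of neuroblasts, at 11 reads or fewer for wor at either stage, were lower as a list (camera adjusted p = 0.000328, adjusted p = 0.00233 with an estimated correlation). The gene Hsp70Bc of the heat shock and dissociation list fell from 245 to 30.8 reads (-3.33 ± 0.85). Hr38 and sr, among the largest decreases of this step, are members of that list too. Over all genes, 260 rose and 450 fell. Without the 4 astrocyte-like libraries in the fit, an alternative chosen after seeing the data, the total was 1095 instead of 710.

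By 6 h, during the period in which γ axons are pruned, most proteasome subunits and a part of the ecdysone response genes had fallen (4 libraries per stage). Of 32 tested proteasome subunit genes, 28 fell and 0 rose (31 and 0 adjusted over the list alone, camera adjusted p = 3.17e-21, adjusted p = 0.000312 with an estimated correlation). Examples were Rpt3 (-1.94 ± 0.20) and Rpn12 (-1.83 ± 0.28). Of 26 tested ecdysone response genes, 9 fell and 3 rose (11 and 4 adjusted over the list alone, camera adjusted p = 0.00052, adjusted p = 0.0854 with an estimated correlation). Eip74EF fell (-3.43 ± 0.35) beside EcR and Eip75B. Of 24 tested channel genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 6.87e-09, adjusted p = 0.00272 with an estimated correlation). They included the potassium channel gene Shab (-4.85 ± 0.37) and para (-2.56 ± 0.24). Of 25 tested Kenyon cell genes, 11 fell and 5 rose (13 and 6 adjusted over the list alone, camera adjusted p = 9.01e-08, adjusted p = 0.0535 with an estimated correlation). Examples were the neuropeptide gene sNPF (-4.00 ± 0.34) and 14-3-3zeta (-2.76 ± 0.19). Of 34 tested receptor genes, 12 fell and 5 rose (15 and 5 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.0978 with an estimated correlation). Dop1R2 fell (-2.56 ± 0.22) and the glutamate receptor genes GluRIA (4.12 ± 0.49) and GluRIB (3.65 ± 0.33) rose.

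The largest single increases from 0 to 6 h were in Osi7 (1.25 to 438 reads, 8.08 ± 0.83), Osi6 (6.77 ± 0.64) and TwdlT (7.10 ± 0.67), of families known from cuticle and trachea, and in Cad96Cb (6.68 ± 0.59), CG4115 (6.19 ± 0.50) and CG8407 (6.18 ± 0.65). Of 29 tested genes of the cuticle and tracheal families, 13 were called higher at 6 than at 0 h and 0 lower, and 2 of 12 tested epithelial marker genes rose and 1 fell, on lists chosen after seeing the data. The largest decreases were in CG11835 (-6.42 ± 0.75), Sytbeta of the synaptotagmin family (-6.18 ± 0.54), CG32137 (-6.02 ± 0.82), MFS3 (-5.62 ± 0.77), the neuropeptide receptor gene TkR86C (-5.53 ± 0.75) and sals (-5.43 ± 0.72). In total 502 genes rose and 464 fell.

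Taken from the third instar directly to 6 h, 589 genes rose and 678 fell, and 927 rose and 841 fell when only these libraries were fitted. On the channel, receptor and synaptic lists, more members fell than rose. Of 24 tested channel genes, 13 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 1.14e-10, adjusted p = 0.00137 with an estimated correlation). Among them were para (-4.33 ± 0.26), Shab (-5.78 ± 0.40) and slo (-6.42 ± 0.59). Of 34 tested receptor genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 9.01e-08, adjusted p = 0.00662 with an estimated correlation). Rdl went down from 10517 to 639 reads (-4.03 ± 0.27), and the nicotinic receptor gene nAChRbeta1 fell (-4.75 ± 0.37). Of 25 tested synaptic genes, 12 fell and 3 rose (14 and 3 adjusted over the list alone, camera adjusted p = 7.82e-07, adjusted p = 0.0302 with an estimated correlation), with Rbp going from 917 to 27.8 reads. Of 25 tested Kenyon cell genes, 13 fell and 4 rose (13 and 4 adjusted over the list alone, camera adjusted p = 7.81e-13, adjusted p = 0.00862 with an estimated correlation), sNPF among them (-5.62 ± 0.37). The named decreases were Rgk3 (-7.14 ± 0.87), CG42700, the transporter gene prt (-6.86 ± 0.60), hec, the chloride channel gene pHCl (2154 to 22.5 reads, -6.70 ± 0.90) and CG30015. Genes of axon guidance and cell adhesion moved both ways, 16 up and 8 down of 53 (camera adjusted p = 0.0617), with the adhesion gene CadN up (2.80 ± 0.31). Besides Osi7, Osi6 and TwdlT, the named increases were CG30053, haf and TwdlE, which was listed at 0 at the third instar.

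From 6 to 18 h (4 libraries per stage) some of these genes rose while a part of the ecdysone response genes fell, Eip74EF and Sox14 again among them. The transcription factor gene ab rose from 17 to 625 reads (5.23 ± 0.32), and CG1850 (6.73 ± 0.65), the hormone receptor gene ETHR (5.23 ± 0.69), the RNA-binding protein gene Rbp9 (4.58 ± 0.64), toc (4.45 ± 0.34) and slgA (8 to 168 reads) rose with it. Of 26 tested ecdysone response genes, 10 fell and 3 rose (12 and 3 adjusted over the list alone, camera adjusted p = 1.03e-06, adjusted p = 0.0145 with an estimated correlation). Examples were Kr-h1 (-5.56 ± 0.60), Eip74EF (-2.81 ± 0.35) and Hr46 (-3.29 ± 0.41). Of 26 tested remodeling regulators, 7 fell and 2 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.004, adjusted p = 0.0215 with an estimated correlation). Among them were Fas2, which encodes a cell adhesion protein (-1.27 ± 0.17), and Mical (-1.81 ± 0.32). Of 24 tested channel genes, 6 rose and 2 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.087, adjusted p = 0.403 with an estimated correlation). They included para (3.52 ± 0.24) and Shab (3.02 ± 0.37). Osi7, Osi6, TwdlT, CG31324 (-7.66 ± 0.56), CG31814 and CG2150 had the largest decreases, and 16 of the 29 cuticle and tracheal genes fell and 2 rose. In total 466 genes rose and 564 fell. The total of 1030 became 1629 when only these 8 libraries were fitted.

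Between 18 and 30 h (4 libraries per stage) fewer genes changed, 65 up and 42 down. The ecdysone-regulated nuclear receptor genes Hr4 (85.2 to 2072 reads, 4.62 ± 0.54) and Hr46 (59 to 879 reads, 3.91 ± 0.41) had large increases, with CG8216, CG12912, CG42327 and CG32137, and the transcription factor gene br fell (-2.03 ± 0.45) with CG1850, Inos, CG3014, Fili and pch2. Of 34 tested receptor genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 4.87e-09, adjusted p = 0.00272 with an estimated correlation). Examples were nAChRbeta1 (2.13 ± 0.34) and Dop1R1 (0.89 ± 0.18). Of 25 tested Kenyon cell genes, 6 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 7.39e-06, adjusted p = 0.111 with an estimated correlation). Leaving out 1 library, for 7 of the 8 libraries (18 h replicate 3 excepted) moved the total by more than 1.5 times, to between 47 and 71 genes. It was 71 with robust variances and no trend, 260 with only the 8 libraries and 199 without the astrocyte-like libraries.

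From 30 h to the adult, more channel, receptor and synaptic genes rose than fell in γ neurons, and more proteasome and ribosomal protein genes fell than rose (4 libraries each, 773 genes higher and 778 lower). Of 24 tested channel genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 1.06e-12, adjusted p = 0.000516 with an estimated correlation). Among them were Ih (4.12 ± 0.26), the calcium channel gene Ca-alpha1D (3.55 ± 0.26) and NaCP60E (5.13 ± 0.61). Of 34 tested receptor genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 2.46e-08, adjusted p = 0.0043 with an estimated correlation). Examples were GluClalpha (3.18 ± 0.36) and nAChRbeta1 (2.56 ± 0.34). Of 25 tested synaptic genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 2.78e-12, adjusted p = 0.00233 with an estimated correlation). They included nSyb (1.71 ± 0.15) and Rim (1.34 ± 0.16). In the adult, of 25 tested Kenyon cell genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 8.54e-08, adjusted p = 0.0535 with an estimated correlation). Examples were sNPF (108 to 4729 reads, 5.44 ± 0.34) and rut (4.38 ± 0.26). Of 32 tested proteasome subunits, 26 fell and 0 rose (30 and 0 adjusted over the list alone, camera adjusted p = 7.81e-13, adjusted p = 0.00272 with an estimated correlation). An example was Prosbeta3 (-1.71 ± 0.24). Of 84 tested ribosomal protein genes, 46 fell and 1 rose (55 and 3 adjusted over the list alone, camera adjusted p = 4.94e-16, adjusted p = 0.199 with an estimated correlation). An example was RpS5a (-1.66 ± 0.15). Of 29 tested cytoskeleton regulators, 11 fell and 4 rose (11 and 4 adjusted over the list alone, camera adjusted p = 0.00544, adjusted p = 0.0413 with an estimated correlation). The gene chic went down from 6897 to 1091 reads (-2.66 ± 0.12). The largest increases were CG5549, CG31808, Tob (7.51 ± 0.90), CR45054, Rgk3 (6.92 ± 0.81) and the junctophilin gene jp (6.86 ± 0.88). The largest decreases were nemy (1042 to 6 reads, -8.10 ± 0.44), ETHR and CG13023 (both listed at 0 in the adult), Hsp67Ba (-6.41 ± 0.77), Hr4 (-6.39 ± 0.54) and Lac.

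**Figure D2:**
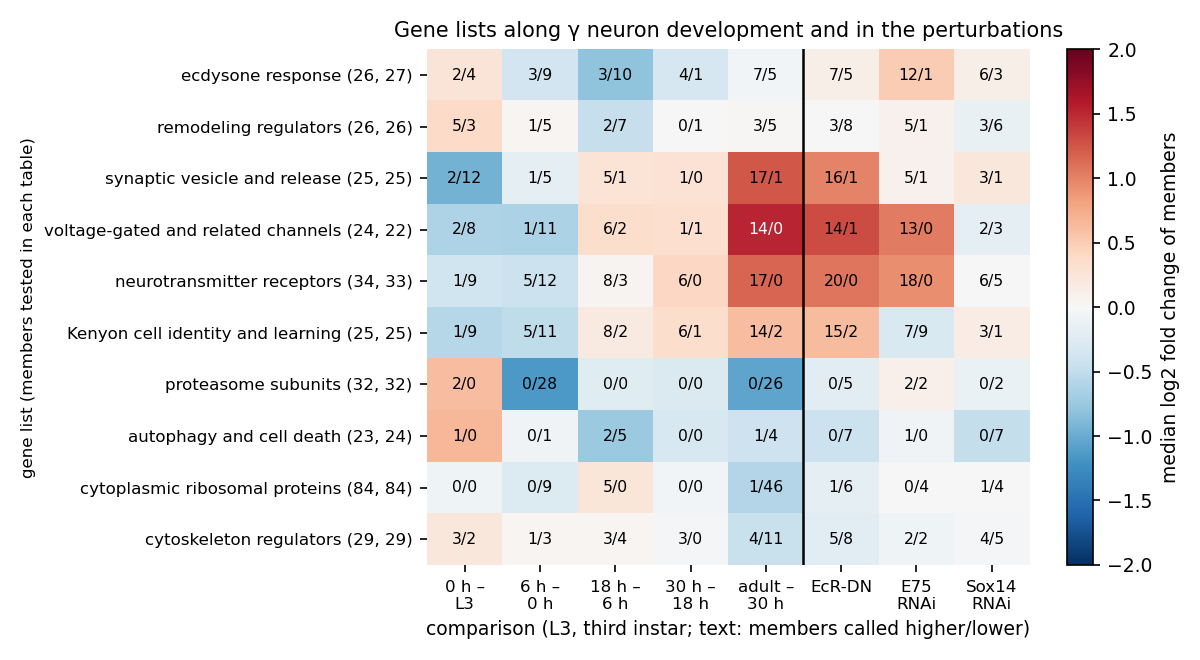
Median log2 fold change (color) of the members of 10 gene lists (y axis, with the members tested in each table) in 5 developmental steps and in the pupal mean of 3 perturbations against control (x axis). Text gives members called higher/lower; 14 of 24 channel genes are higher and 0 lower in the adult than at 30 h.

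Adult γ neurons were next set against other adult brain cells, 4 libraries each, to ask which transcripts set them apart. The driver lines, and so the strains, differed between these cell types. Against αβ neurons, the transcription factor gene ab (1107 against 32.5 reads, 5.05 ± 0.32), the kinase subunit gene Pka-C3 (6.88 ± 0.96), the receptor gene Lgr3 (6.28 ± 0.58), the transcription factor gene zfh2 (5.35 ± 0.45), the glypican gene dlp (5.28 ± 0.74), GstD11 (7.48 ± 0.61), Mocs1 (7.05 ± 0.53), PH4alphaNE1, danr and CG1504 were the named genes higher in γ neurons. The receptor genes Lgr1 (-6.52 ± 0.68), Dh44-R2 (-5.68 ± 0.78) and rk (-5.42 ± 1.02), with SP1173 (-7.26 ± 0.66), CG11406, CG31814, CG10738, crb and the eye color marker w, were lower in γ neurons, and Gyc-89Db was listed at 0 there against 58.8 reads. The gene w was at 1.25 reads in adult γ neurons and 153 in αβ neurons. It was also at 98.8 in neurons outside the mushroom body and 172 in astrocyte-like cells, and whether this follows the strains was not tested. Of 25 tested Kenyon cell genes, 10 were higher and 1 lower (11 and 5 adjusted over the list alone, camera adjusted p = 1.23e-07, adjusted p = 0.055 with an estimated correlation). Among them were Imp (4.23 ± 0.34) and mamo (4.74 ± 0.39). Of 29 tested genes of the dpr and DIP surface protein families, 4 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.00208, adjusted p = 0.0439 with an estimated correlation), among them dpr17 (4.26 ± 0.65), DIP-gamma, dpr16 and dpr12. The collagen genes Cg25C (-3.79 ± 0.66) and vkg and the matrix gene SPARC, on the hemocyte list, were lower in γ neurons, 3 of 5 tested with 3 adjusted over the list alone (camera adjusted p = 0.000145). In all 330 genes were higher and 295 lower.

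Against adult neurons outside the mushroom body, 379 genes were higher in γ neurons and 825 lower. Of 25 tested Kenyon cell genes, 19 were higher and 2 lower (19 and 3 adjusted over the list alone, camera adjusted p = 1.39e-32, adjusted p = 7.63e-05 with an estimated correlation). They included ey (2.78 ± 0.17), Pka-R2 (2.87 ± 0.19) and mub (2.30 ± 0.18), and the nuclear receptor gene Hr51 (278 against 25 reads) was among the largest differences with Mocs1, CG34232, CG2022, CG13055, sals, CG6912, GstD11, CG33098 and CAH2. Lower were the transcription factor genes Optix (-6.30 ± 0.88), fkh, Ets65A and Sox21b, the neuropeptide genes Dh31 (-5.97 ± 0.92) and Tk (-5.82 ± 0.89), CG6123, CG34155, beat-Vc and CG32532 (listed at 0 in γ neurons), and the glutamate transporter gene VGlut (-5.23 ± 0.95). Of 29 tested dpr and DIP genes, 14 were lower and 1 higher (14 and 2 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.0132 with an estimated correlation). Of 53 tested guidance and adhesion genes, 24 were lower and 5 higher (28 and 7 adjusted over the list alone, camera adjusted p = 0.00416, adjusted p = 0.439 with an estimated correlation). Of 19 tested glial genes, 4 were lower and 0 higher (4 and 0 adjusted over the list alone, camera adjusted p = 0.0579, adjusted p = 0.285 with an estimated correlation), for example Eaat1 (-4.06 ± 1.07). Both photoreceptor genes tested, norpA (-2.67 ± 0.49) and ninaC, were lower.

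Against astrocyte-like cells, 2571 genes were higher in γ neurons and 1741 lower. Neuronal lists were higher, 28 of 34 receptor genes (camera adjusted p = 1.06e-12, and adjusted p = 0.000516 with an estimated correlation) and 21 of 25 synaptic genes (camera adjusted p = 2.53e-13, and adjusted p = 0.00159 with an estimated correlation), among them nSyb (3.60 ± 0.15) and brp (3.89 ± 0.18). Of 19 tested glial markers, 16 were lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 1.69e-10, adjusted p = 0.000516 with an estimated correlation). Examples were nrv2 (-5.20 ± 0.21) and htl (-8.14 ± 0.60). Of 84 tested ribosomal protein genes, 79 were lower and 0 higher (80 and 0 adjusted over the list alone, camera adjusted p = 8.42e-29, adjusted p = 0.0685 with an estimated correlation). The largest differences in favor of γ neurons were Pka-C3 (9.48 ± 0.96), GstD11, CG34357, Sema-2b (7.48 ± 0.47), Rgk3, CG13055, CG42404, CG42817, Ca-beta and pgant2. Those in favor of astrocyte-like cells were CG9377 (-12.30 ± 0.74), CG31705, vkg (-10.71 ± 0.63), CAH1, zfh1 (-10.45 ± 0.78), CG16743, CG7888, Msr-110 and pnt, with CG15784 listed at 0 in γ neurons. Astrocyte-like libraries had the lowest mean correlation with their own group, 0.733, and fitting these 8 libraries alone gave 2453 instead of 4312 genes. Of these, 1252 were higher in γ neurons and 1201 lower, so the excess of higher genes mostly went. Estimated depth of the astrocyte-like libraries was 0.476 to 0.859 megareads. They had 5850 to 7308 genes with at least 1 read, against 7235 to 7721 in adult γ neurons, and the part of depth in the excess was not tested.

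In the perturbation table the targeted genes were checked first. In Sox14 RNAi libraries (3 per stage) Sox14 was lower than in control at the third instar (-2.66 ± 0.26) and at 0 h (-2.87 ± 0.23), and did not pass the test at 6 h (0.20 ± 0.26) or 12 h (-0.12 ± 0.23), when control levels were also low. In libraries labelled E75 RNAi (2 or 3 per stage) the Eip75B transcript was not called lower at any stage. At the third instar it lay in the direction of the label without passing the test, at 14881 to 22294 against 25956 to 33983 reads (-0.68 ± 0.25, adjusted p = 0.152). It did not pass the test at 0 h (-0.07 ± 0.25) and was higher at 6 h (1.24 ± 0.25). Directions below are those of the libraries labelled E75 RNAi. In EcR-DN libraries (2 or 3 per stage), EcR was lower at the third instar (-1.95 ± 0.21) and higher at 6 h (2.91 ± 0.21), and reads of a transgene were not told apart from those of the gene. Eip75B (-2.60 ± 0.25 at the third instar, -1.66 ± 0.22 at 0 h) and Sox14 (-3.59 ± 0.26 and -2.30 ± 0.23) were lower in EcR-DN at both stages, and Sox14 was higher at 6 h (1.69 ± 0.26). In libraries labelled E75 RNAi, Sox14 was lower at the third instar (-0.90 ± 0.26) and higher at 6 h (2.97 ± 0.26) and 12 h (2.41 ± 0.26). EcR was higher in them at 0 h (1.09 ± 0.21), 6 h (1.77 ± 0.21) and 12 h (0.70 ± 0.21). The rise of Eip75B at 6 h was also seen in Sox14 RNAi libraries (1.02 ± 0.25).

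**Figure D3:**
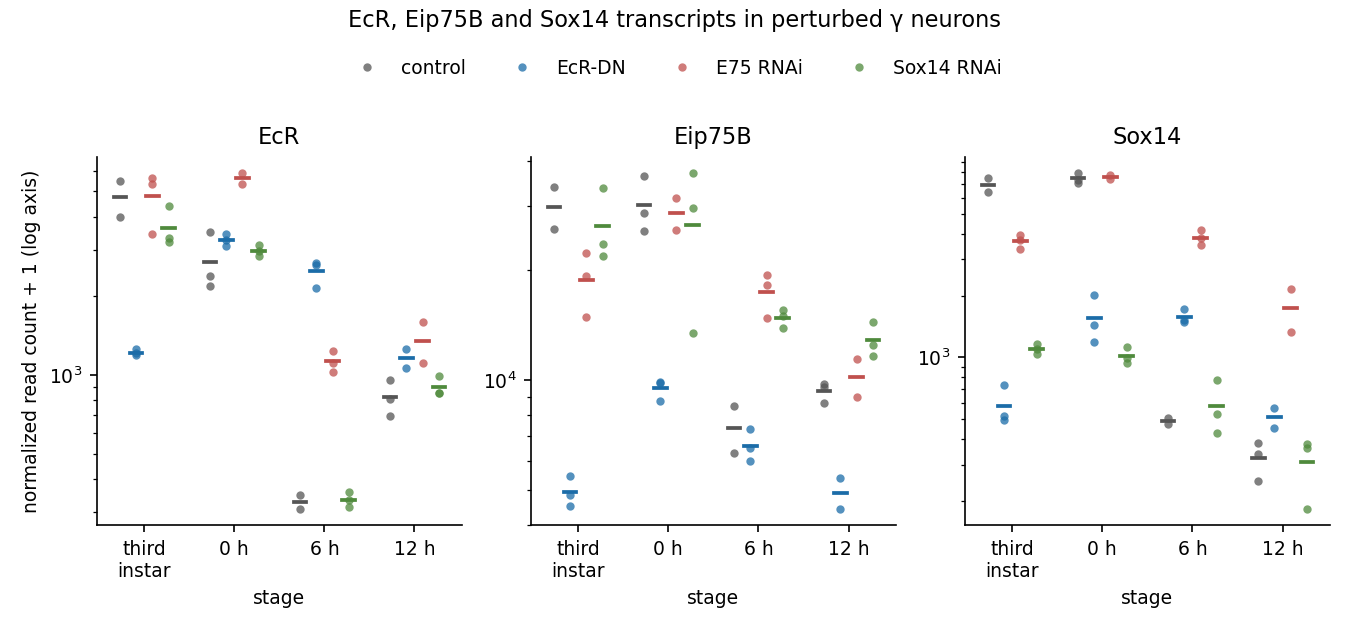
Normalized reads of EcR, Eip75B and Sox14 (log axis, value + 1) in perturbation libraries at 4 stages (x axis). Points are libraries, bars are group means and colors are genotypes. Eip75B in libraries labelled E75 RNAi lies above control at 6 h.

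In EcR-DN, transcripts of most tested synaptic, channel and receptor genes were higher than in control in the pupa. Over the mean of 0, 6 and 12 h (8 libraries of each genotype), the activity-induced nuclear receptor gene Hr38 was at 1672 reads against 25.4 in control (5.91 ± 0.55) and the aldolase gene Ald at 5114 against 151 (5.14 ± 0.38). Rgk3 (4.99 ± 0.48), Tob (5.21 ± 0.80), CG4678, CG11000, CG8398, CG43778, CR45054 and CG16779 were the other named genes higher in EcR-DN. The named genes lower in EcR-DN were CG5958 (-3.71 ± 0.63), Rab9 (-2.81 ± 0.66), the secreted protein gene sca (288 against 1686 reads, -2.50 ± 0.23), CG15097, CR44997, bip1, haf (-2.16 ± 0.69), Hsp67Bc (-2.13 ± 0.20), CG10713 and CG7650.

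Of 22 tested channel genes, 14 were higher and 1 lower (14 and 2 adjusted over the list alone, camera adjusted p = 3.51e-12, adjusted p = 0.00684 with an estimated correlation). Among them were slo (4.15 ± 0.35), para (2.92 ± 0.21) and Shab (2.63 ± 0.18). Of 33 tested receptor genes, 20 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 2.82e-10, adjusted p = 0.00328 with an estimated correlation). Rdl was at 13538 against 2051 reads (2.80 ± 0.22). Of 25 tested synaptic genes, 16 were higher and 1 lower (17 and 2 adjusted over the list alone, camera adjusted p = 1.22e-10, adjusted p = 0.0102 with an estimated correlation). Examples were Rbp (3.18 ± 0.27) and Syt1 (1.72 ± 0.15). Of 25 tested Kenyon cell genes, 15 were higher and 2 lower (18 and 3 adjusted over the list alone, camera adjusted p = 1.88e-08, adjusted p = 0.0829 with an estimated correlation). An example was sNPF (2.89 ± 0.17). Of 24 tested autophagy and cell death genes, 7 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.000576, adjusted p = 0.00512 with an estimated correlation). Diap1 (-1.04 ± 0.12), Dronc (-1.59 ± 0.30) and Atg7 (-1.20 ± 0.28) were lower. The ecdysone response list split, 7 higher, among them br (3.60 ± 0.17) and ftz-f1 (3.61 ± 0.33), and 5 lower of 27 (camera adjusted p = 0.365). At 0 h, 3 of 18 neuroblast and cell cycle markers were higher in EcR-DN and 0 lower, with wor at 21 against 0.667 reads and mira at 54 reads, listed at 0 in control. Of all genes 919 were higher and 508 lower. Stage by stage the counts were 332 and 381 at the third instar, 899 and 555 at 0 h, 421 and 172 at 6 h, and 347 and 70 at 12 h. With only the compared groups fitted, those at the third instar were 494 and 407. Leaving out 1 library took the total from 593 to as low as 355 at 6 h and from 417 to 211 at 12 h. Proteasome subunits were mostly lower at the early stages. Of these, 24 were lower and 0 higher of 32 tested at the third instar (27 and 0 adjusted over the list alone, camera adjusted p = 1.83e-23, adjusted p = 0.00211 with an estimated correlation) and 30 were lower and 0 higher of 32 tested at 0 h (30 and 0 adjusted over the list alone, camera adjusted p = 4.05e-23, adjusted p = 0.00211 with an estimated correlation). The remodeling regulators were lower as a list at the third instar (camera adjusted p = 0.000475, and adjusted p = 0.026 with an estimated correlation).

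In libraries labelled E75 RNAi, most tested channel and receptor genes and a part of the ecdysone response genes were higher than in control in the pupa (7 libraries, against 8 control libraries). The neuropeptide receptor gene SIFaR was at 769 against 8.33 reads (7.99 ± 0.72), Rgk3 at 1257 against 14.6 (7.40 ± 0.50), and the channel gene Trpgamma (6.45 ± 0.77), the neuropeptide gene Capa (5.37 ± 0.56), CG13054, CG11000, CG6310, CG8398 and the pair inaF-D and inaF-B, whose values were identical in the libraries, were also higher. Lower were rho, a protease gene of growth factor signaling (-3.35 ± 0.34), ab (-3.26 ± 0.40), the receptor gene AstC-R1 (-3.41 ± 0.61), MRE16, CG13300, nolo, CG1504, Cyp9c1, CG5953 and CG42747. Of 27 tested ecdysone response genes, 12 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 1.68e-11, adjusted p = 0.000124 with an estimated correlation). Among them were ftz-f1 (4.39 ± 0.34), Hr46 (3.35 ± 0.18) and br (2.43 ± 0.18). Of 22 tested channel genes, 13 were higher and 0 lower (15 and 2 adjusted over the list alone, camera adjusted p = 6.46e-15, adjusted p = 0.0035 with an estimated correlation). An example was slo (4.97 ± 0.36). Of 33 tested receptor genes, 18 were higher and 0 lower (22 and 1 adjusted over the list alone, camera adjusted p = 2.31e-14, adjusted p = 0.000716 with an estimated correlation). An example was GluRIA (2.86 ± 0.23). Of 25 tested synaptic genes, 5 were higher and 1 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.0176, adjusted p = 0.477 with an estimated correlation). Kenyon cell genes went both ways, 7 higher, such as rut (2.75 ± 0.20), and 9 lower, such as Fas2 (-1.81 ± 0.14), of 25 (camera adjusted p = 0.893). In total 607 genes were higher and 483 lower, a balance that turned without E75 RNAi replicate B of 0 h. With only the compared groups fitted, these totals were 481 and 268. Counts by stage were 135 and 142 at the third instar, 300 and 284 at 0 h, 411 and 315 at 6 h, and 278 and 105 at 12 h. With only the compared groups fitted, they were 206 and 106, 163 and 78, 314 and 100, and 160 and 53. Without E75 RNAi replicate B of 0 h, those at 0 h were 249 and 417. Leaving out 1 library took the total from 726 to as low as 454 at 6 h and from 383 to 239 at 12 h.

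In Sox14 RNAi, a part of the autophagy and cell death genes was lower than in control in the pupa, and none was higher (9 libraries, against 8 control libraries). Higher were the nicotinic receptor genes nAChRalpha3 (183 against 19.5 reads, 3.64 ± 0.58) and nAChRalpha7 (2.60 ± 0.36), the growth factor gene pyr (4.14 ± 0.54), the receptor gene CCKLR-17D1 (2.62 ± 0.45), CG9541, CG13924, CG12065, CR40469, nord and the body color marker y (6.52 ± 0.63), which was above the highest control library in all 12 Sox14 RNAi libraries. The named genes lower in Sox14 RNAi were CG31814 (-3.96 ± 0.50), haf (-3.78 ± 0.66), Dgk (-3.27 ± 0.70), the channel gene CngA (-3.04 ± 0.51), dpr20 (-2.87 ± 0.51), Rab9, CG5958, CG34393, Cyp9c1 and CG45002. Of 24 tested autophagy and cell death genes, 7 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 7.24e-05, adjusted p = 0.00211 with an estimated correlation). They included Atg3 (-1.11 ± 0.17), Atg7 (-1.66 ± 0.27) and Dronc (-1.82 ± 0.29). Of 26 tested remodeling regulators, 6 were lower and 3 higher (6 and 3 adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.229 with an estimated correlation), with Fas2 lower (-1.49 ± 0.13). Among guidance genes, which were 6 higher and 8 lower of 53 (camera adjusted p = 0.548), Sema-2b was lower (-2.75 ± 0.17). Channel genes were 2 higher and 3 lower of 22. Of 20 tested glial markers, 3 were lower and 1 higher, nrv2 among them (-1.17 ± 0.23). In total 456 genes were higher and 549 lower. By stage the counts were 19 and 132 at the third instar, 309 and 431 at 0 h, 198 and 320 at 6 h, and 81 and 58 at 12 h. With only the compared groups fitted, they were 0 and 13, 77 and 233, 227 and 338, and 36 and 27. Leaving out 1 library took the total from 518 to as low as 321 at 6 h and from 139 to 70 at 12 h.

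**Figure D4:**
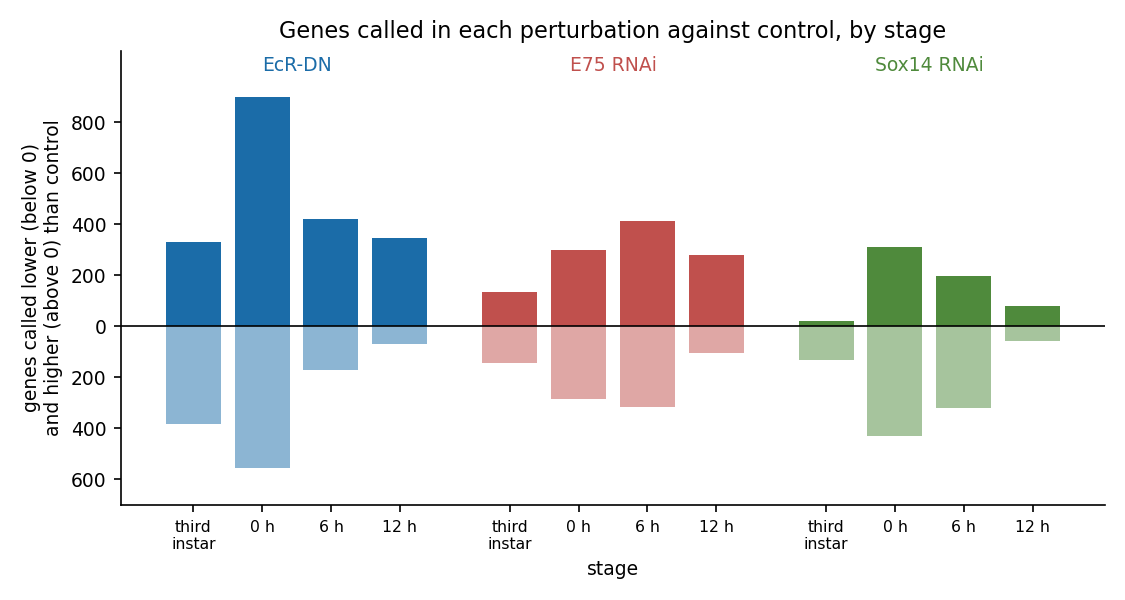
Genes called higher (above 0) and lower (below 0, paler) than control in each perturbation at 4 stages (x axis). EcR-DN at 0 h has 899 higher and 555 lower genes.

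Controls had 2 libraries at the third instar and 2 at 6 h, and single stage counts leaned on them. Without control replicate C of the third instar, the totals at that stage fell from 713 to 317 in EcR-DN, from 277 to 112 in libraries labelled E75 RNAi and from 151 to 56 in Sox14 RNAi. The position of the Sox14 RNAi libraries A of the third instar and of 0 h is also open. On an axis from the other Sox14 RNAi libraries of the third instar (0) to those of 0 h (1) they lay at 1.18 and -0.317, and the control libraries of the third instar at 0.763 and 1.09.

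The perturbations were then tested directly against each other over the pupal mean, since they shared the control libraries. EcR-DN minus Sox14 RNAi gave 848 genes higher and 427 lower, EcR-DN minus E75 RNAi 1223 and 753, and E75 RNAi minus Sox14 RNAi 940 and 1000. In EcR-DN relative to Sox14 RNAi, of 22 tested channel genes, 16 were higher and 0 lower (16 and 1 adjusted over the list alone, camera adjusted p = 8.45e-17, adjusted p = 0.00211 with an estimated correlation). In the same comparison, of 33 tested receptor genes, 19 were higher and 1 lower (19 and 2 adjusted over the list alone, camera adjusted p = 2.5e-11, adjusted p = 0.00211 with an estimated correlation). Relative to libraries labelled E75 RNAi, EcR-DN had 11 of 27 ecdysone response genes lower and 2 higher (11 and 2 adjusted over the list alone, camera adjusted p = 2.14e-05, adjusted p = 0.00472 with an estimated correlation). In the same direction of subtraction, 15 of 25 Kenyon cell genes were higher and 2 lower (17 and 2 adjusted over the list alone, camera adjusted p = 6.01e-07, adjusted p = 0.132 with an estimated correlation). Autophagy and cell death genes were higher in libraries labelled E75 RNAi than in Sox14 RNAi, 10 of 24 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00198, adjusted p = 0.0093 with an estimated correlation).

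Across 8656 genes, which are not independent replicates, the pupal effects of EcR-DN and Sox14 RNAi correlated at r = 0.469, those of EcR-DN and E75 RNAi at 0.376 and those of E75 RNAi and Sox14 RNAi at 0.253. Simulated unchanged groups set against the same controls gave mean r of 0.519, 0.484 and 0.501, above each of these. With the controls split into 2 parts so that no library was shared, the median r over 36 splits was 0.218, 0.186 and 0.0464. The covariances were 0.328, 0.325 and 0.185 against simulated means of 0.133, 0.134 and 0.133. Genes called higher in both numbered 212, 306 and 112, where independence (n1 × n2 / N) would give 48.4, 64.4 and 32.0, and with split controls the medians were 103, 220 and 57.5. Genes called lower in both numbered 231, 78 and 87, against 32.2, 28.3 and 30.6 by independence and medians of 118.5, 34 and 29.5 with split controls. The values by independence were taken from calls against all 8 control libraries, and each split part held 4. The medians are therefore not comparable with them, and a fall under splitting can also come from fewer controls. The simulated groups shared 0 calls, but no gene was changed in them. This count therefore cannot show how many shared calls common controls add where genes do change. Opposite calls numbered 52, 90 and 108, against 85.05, 86.90 and 63.94 by independence. They were thus fewer for EcR-DN and Sox14 RNAi, close for EcR-DN and E75 RNAi, and more for E75 RNAi and Sox14 RNAi. Shared controls alone push effects to the same sign, as in 67.3%, 66.1% and 66.7% of genes in the simulated groups. Fewer or close counts of opposite calls therefore cannot be read as a relation between perturbations. In all 3 perturbations, 77 genes were higher and 38 lower.

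The design also asks which part of the larva-to-6 h change was altered in each perturbation. Of 7862 genes tested in both tables, which share no library, 582 were higher and 676 lower in γ neurons at 6 h than at the third instar. In EcR-DN at 6 h, 356 of the 676 developmental decreases (52.7%, odds ratio 131 against other genes) were higher than in control and 0 lower, and 94 of the 582 increases (16.2%, odds ratio 28.4) were lower and 0 higher. Libraries labelled E75 RNAi had 197 of the 676 higher (29.1%, odds ratio 15.5, Fisher's exact p = 4.35e-115) and 32 lower, and 64 of the 582 lower (odds ratio 3.82, Fisher's exact p = 7.01e-16) and 23 higher. Sox14 RNAi had 99 of the 676 higher (14.6%, Fisher's exact p = 1.53e-57) and 23 lower, and 130 of the 582 lower (22.3%, odds ratio 14.2, Fisher's exact p = 8.78e-77) and 8 higher. The median log2 effect on the 582 increases was -0.82 in EcR-DN, -0.28 in libraries labelled E75 RNAi and -0.65 in Sox14 RNAi. On the 676 decreases it was 1.46, 0.35 and 0.28. The higher count of lowered increases in Sox14 RNAi than in EcR-DN was thus not a larger median effect. The tests are two-sided and count genes, not animals. The 94 increases lower in EcR-DN became 62 with robust variances and no trend and 161 with a pseudocount of 10.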

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

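The tests of the cuticle families' need for Sox14, of an exchange of the libraries A, of y and v as construct markers, the 3 tests of y under low Sox14 transcript, and the counts over splits of the libraries were chosen only after the result was seen. The other tests below were written down before their value was seen.

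Genes of cuticle and tracheal families stood high in the 6 h γ neuron libraries, where their summed level was 2312 reads (SD 298, n = 4), against 832 reads at 0 h and 810 at 9 h, and it was 5619 in control libraries at 6 h. If cells of epidermis or trachea were among the sorted cells, the families should vary together between libraries of a group. Their mean residual correlation in the perturbation table, 0.0552 over 51 genes, was at percentile 100 of 1000 random sets matched on level (random median 0.00804). In the developmental table it was 0.0667 against a random maximum of 0.0426. The prediction was met, but the random sets were matched on level alone, and genes regulated together within γ neurons can also pass. The test therefore cannot tell such cells from a program of the γ neurons. The sort on a γ neuron reporter should remove such cells, and timing differences within a stage stay open. Of 12 epithelial markers, 2 rose and 1 fell from 0 to 6 h, with grh at 9, shg at 18.5 and tyn, the highest, at 363 reads at 6 h, and tyn and sdt were also expressed at 0 and 18 h. A program of the γ neurons that needs Sox14 cannot be told apart from a difference in dissection between genotypes: over the 13 genes of the families called higher at 6 h, the median Sox14 RNAi library at 6 h held 3.05% of the lowest control library (42, 866 and 111 reads against 3643 and 4856, with EcR-DN at 954 to 1489 and E75 RNAi at 1923 to 2049), but Sox14 RNAi was above control in library B of the third instar (728 against 48 and 65) and library A of 0 h (554 against 81 to 151), and over all genes of the families Sox14 RNAi held 879, 1770 and 741 reads against 4893 and 6344.

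On an axis of 707 genes from the other Sox14 RNAi libraries of the third instar (0) to those of 0 h (1), its library A of the third instar lay at 1.18 and its library A of 0 h at -0.317. The others, which define the axis, lay at 0.129 and -0.129, and at 1.04 and 0.955, and control libraries lay at 0.763 and 1.09 for the third instar and at 2.40 to 2.43 for 0 h. An exchange of the labels cannot be told apart from a displacement of the other libraries, since library A of the third instar lies beside the control libraries of its stage. Low depth was argued against, since over 411 genes with a mean of at least 200 the positions were 1.17 and -0.334. With the labels exchanged, calls went from 151 to 236 at the third instar (117 shared) and from 740 to 780 at 0 h (555 shared), and differences in staging stay open.

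The body and eye color genes y and v were high in Sox14 RNAi: y was above control at the pupal mean (6.52 ± 0.63, adjusted p = 1.63e-10 in limma) and v too (2.15 ± 0.58, adjusted p = 0.00911 in limma). Together they lay above the highest control library in 22 of 24 values (y 12 of 12, v 10 of 12), which restates the pattern, and of 12 tested chromosome neighbours 1 was called, C901, which was lower (-1.87). Whether the inserted construct carries these genes as markers cannot be told apart from other causes, since the labels do not describe it. For y under low Sox14 transcript, the first test asked whether at least 1 of 6 EcR-DN libraries at the third instar and 0 h, where Sox14 is low, had y above the highest control library, and 2 did (highest 15 reads, against 7), which met its bound, but 2 libraries labelled E75 RNAi also passed this bar with 9 reads, 1 at the third instar, where mean Sox14 was lower than in control (3693 against 6921 reads), and 1 at 12 h, where it was higher (1733 against 322). After that value was seen, 2 tests of size were added and the reading of the first was changed, and these argue against low Sox14 transcript being enough to raise y: mean y in EcR-DN at the third instar was 5.50% of that in Sox14 RNAi (7 against 127 reads, at 580 against 1095 reads of Sox14), and in the 5 control libraries at 6 and 12 h, without EcR-DN and with less Sox14 than every Sox14 RNAi library at the third instar, the highest y was 2 against a lowest y of 77 in the latter.

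Of 176 sets of 4 libraries (1 measure in 1 group each), 11 had a library far from the others, where chance flags about 1 in 20 groups and 8.8 would be expected. The values are the gap to the nearest other library divided by the range. The mean correlation with the own group stood apart in replicate 3 of 0 h (0.866 against 0.908 to 0.913, value 0.881) and in replicate 4 of 27 h (0.941 against 0.936 to 0.937, value 0.831). Sox14 stood apart in replicate 4 of 9 h (150 reads against 64 to 68, value 0.953), replicate 2 of 15 h (60 against 91 to 94, value 0.912) and replicate 2 of αβ neurons (202 against 8 to 18, value 0.948). Genes detected stood apart in replicate 1 of neurons outside the mushroom body (8294 against 8072 to 8101, value 0.869), and Eip75B in replicate 4 of astrocyte-like cells (2141 against 1218 to 1284, value 0.928). Among named genes, ETHR stood apart in replicate 4 of 18 h (106 against 55 to 57, value 0.961), Lac in replicate 4 of 30 h (160 against 100 to 108, value 0.867), dlp in replicate 3 of adult γ neurons (263 against 187 to 194, value 0.908) and Gyc-89Db in replicate 3 of αβ neurons (29 against 64 to 71, value 0.833).

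Effects on the targeted genes differed between stages in 14 of 18 tests of the difference itself. In EcR-DN, the log2 effect at 6 h exceeded that at 0 h by 2.60 for EcR, 1.51 for Eip75B and 3.99 for Sox14, and that at the third instar by 4.86, 2.44 and 5.28. In libraries labelled E75 RNAi, it exceeded that at 0 h by 1.31 for Eip75B and 2.94 for Sox14, and that at the third instar by 1.77 for EcR, 1.92 for Eip75B and 3.87 for Sox14. In Sox14 RNAi, it exceeded that at 0 h by 1.30 for Eip75B and 3.07 for Sox14, and that at the third instar by 2.86 for Sox14. The Eip75B difference leans on Sox14 RNAi library A of 0 h, whose position is open (13480 reads against 36983 and 29604). It was not tested without that library. Control Sox14 was at 6921 reads at the third instar, 7445 at 0 h and 487 at 6 h, which left less room for a decrease at 6 h.

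In 35 splits each of the developmental libraries, only 1 split, the real one, reached the count of called genes. That share is under 0.05 for each comparison and was not adjusted over the comparisons. Splits cannot address a difference, such as one of handling, that runs with the groups. The real and highest other counts were 710 and 493 (0 h against the third instar), 966 and 140 (6 h against 0 h), 1267 and 701 (6 h against the third instar), 1030 and 66 (18 h against 6 h), 107 and 4 (30 h against 18 h), 1551 and 157 (adult against 30 h), 625 and 135 (αβ neurons), 1204 and 69 (neurons outside the mushroom body) and 4312 and 2701 (astrocyte-like cells). In 100 drawn splits each, the real split alone also reached the count for EcR-DN (1427 and 976), E75 RNAi (1090 and 624) and Sox14 RNAi (1005 and 718) over the pupal mean. The same holds for EcR-DN minus Sox14 RNAi (1275 and 706), EcR-DN minus E75 RNAi (1976 and 1329), E75 RNAi minus Sox14 RNAi (1940 and 1148) and the F test among stages (3619 and 191). For the third instar against the second (13 and 9), EcR-DN at 0 h (1454 and 3), Sox14 RNAi at 0 h (740 and 33) and Sox14 RNAi at 12 h (139 and 4), the 10 splits are too few for a share under 0.05.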

How the results depend on the processing

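The alternatives without the astrocyte-like libraries, without the Sox14 RNAi libraries A of the third instar and 0 h, and without the cuticle and tracheal families were chosen after seeing the data. Of the named genes' called values, run under the alternatives counted at the end and without the Sox14 RNAi libraries A, none reversed. These genes were chosen mainly for large changes without overlap or for small p-values, so a reversal was unlikely by selection. The balance of higher and lower calls turned under at least 1 alternative in 10 of 28 comparisons: 6 h against 0 h and against the third instar, 30 h against 18 h, adult against 30 h, αβ neurons, EcR-DN at the third instar, E75 RNAi at the third instar, at 0 h and over the pupal mean, and E75 RNAi minus Sox14 RNAi. With only the compared groups it turned in 7, among them EcR-DN at the third instar (494 higher and 407 lower) and 6 h against the third instar (927 and 841, and 866 and 823 without the astrocyte-like libraries). Of 35 counts, 35 stayed within 1.5 times with median-ratio rescaling and with the replicate block, 31 with limma without trend and with robust variances, 34 with no filter, 34 with the stricter filter, 33 with a pseudocount of 10 and 24 with only the compared groups. The rescaling factors were 1.014 to 1.048 for developmental and 1.028 to 1.058 for perturbation libraries. The rescaling thus changed the values little, and its stable counts say little about other normalizations. The replicate block assumed that numbers are paired, and little sign of pairing was seen: the mean residual correlation of libraries with the same number was 0.00229 and -0.00275, and 20 of 64 and 11 of 43 libraries lay closest to their own number. After rescaling, the median of all genes stood at 0.11 for 6 h against the third instar, -0.15 for γ neurons against neurons outside the mushroom body, 0.29 against astrocyte-like cells, 0.17 for EcR-DN at 0 h, -0.11 and -0.13 for libraries labelled E75 RNAi over the pupal mean and at 6 h, 0.18 for EcR-DN minus E75 RNAi and -0.18 for E75 RNAi minus Sox14 RNAi. Shares of higher genes among called genes moved by between -2.58 and 1.07 percentage points under it. Depth and spread limit small changes: in simulated data 10% of genes changed by log2 1 and 52% of those changed by log2 2 were called between 18 h and 6 h. The shares were 31% and 65% for the EcR-DN pupal mean, and 0% and 30% for Sox14 RNAi at the third instar, with 2 to 4 unchanged genes called. Among genes with a mean level of at least 50 they were 32.1% and 88.6%, 66.7% and 96.2%, and 0% and 64.3%. Only 200 genes were changed in each simulation, against 1030 called in the data between 18 h and 6 h. The adjusted threshold was therefore stricter in the simulation, and recovery in the data may be higher.

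Counts moved by more than 1.5 times as follows, and the cause was not tested except that fewer libraries were fitted in some. With robust variances and no trend, 30 h against 18 h gave 71 genes, Sox14 RNAi at the third instar 86 and at 12 h 91, and 62 genes were higher at 6 h and lower in EcR-DN. The third instar against the second gave 48 with no filter, 3 with the stricter filter, and 23 with a pseudocount of 10, under which 161 genes were higher at 6 h and lower in EcR-DN. With only the compared groups, the third instar against the second gave 0, 18 h against 6 h 1629, 30 h against 18 h 260, astrocyte-like cells 2453, E75 RNAi 241 at 0 h, 414 at 6 h and 213 at 12 h, and Sox14 RNAi 13 at the third instar, 310 at 0 h and 63 at 12 h. Under that alternative 147 genes were higher at 6 h and lower in EcR-DN. Without the astrocyte-like libraries, the third instar against the second gave 30, 0 h against the third instar 1095 and 30 h against 18 h 199. With an estimated correlation, 31 camera calls were made in the developmental and 42 in the perturbation table. With the controls split, the overlaps fell to 103 (EcR-DN and Sox14 RNAi, both higher) and 118.5 (both lower), to 34 (EcR-DN and E75 RNAi, both lower), and to 57.5 and 29.5 (E75 RNAi and Sox14 RNAi, both higher and both lower).

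Leaving out single libraries gave 5 to 21 for the third instar against the second (5 without replicate 3 and 21 without replicate 1 of the second instar) and 47 to 75 for 30 h against 18 h (57, 47 and 60 without replicates 1, 2 and 4 of 18 h, and 50, 71, 50 and 53 without replicates 1 to 4 of 30 h). At the third instar it gave 317 to 614 for EcR-DN, 112 to 224 for E75 RNAi and 56 to 157 for Sox14 RNAi. Control replicate C of that stage gave the low ends, and without replicate B they were 459, 135 and 66. At 6 h it gave 355 to 462 for EcR-DN (355 without control replicate A, 373 without C), 454 to 719 for E75 RNAi (454 without control replicate C) and 321 to 411 for Sox14 RNAi (326 without control A, 321 without control C, 345 without its replicate A). At 12 h it gave 211 to 356 for EcR-DN (211 and 236 without its replicates A and B), 239 to 329 for E75 RNAi (239 without its replicate A) and 70 to 119 for Sox14 RNAi (83, 79 and 76 without control A, B and C, and 70 and 80 without its replicates A and C). A lone library left in a group is assumed to vary like the others. Of 1442 values of named genes, those weaker and stronger were 2 and 2 with rescaling, 90 and 1 with robust variances and no trend, 1 and 10 (of 1395) with the stricter filter, 27 and 0 with no filter, 14 and 22 with a pseudocount of 10, 14 and 4 with the replicate block and 114 and 27 with only the compared groups.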

Other observations

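The comparisons with developmental stages below were written down before their values were seen, and no test in this part was chosen after its result was seen.

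Of the lists whose F test counts are not yet given, the heat shock and dissociation response list had 18 of 18 genes that differed among γ neuron stages, neuroblast and cell cycle 12 of 13, axon guidance and cell adhesion 39 of 53, dpr and DIP surface proteins 22 of 29, cytoskeleton regulators 21 of 29, channels 20 of 24, remodeling regulators 21 of 26, autophagy and cell death 15 of 23, insulin and TOR signalling 10 of 16, glial markers 9 of 19, TGF-beta and BMP signalling 6 of 14, hemocyte markers 3 of 5, photoreceptor markers 1 of 2 and fat body markers 0 of 1. Small heat shock protein genes also changed, with Hsp23 rising from 0 to 6 h (1.71 ± 0.40) and falling from 6 to 18 h (-1.46 ± 0.40), and Hsp67Bc falling from 30 h to the adult (3306 to 79 reads, -5.45 ± 0.63). Of the insulin and TOR genes, 3 fell and 0 rose from 30 h to the adult, InR (494 to 94.8 reads, -2.39 ± 0.29), Akt1 (-1.02 ± 0.32) and Tor (-1.24 ± 0.38).

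At the third instar, EcR-DN had 3 of 15 insulin and TOR genes lower and 0 higher, the kinase genes Pdk1 (448 against 3665 reads, -3.02 ± 0.27), S6k (-1.38 ± 0.20) and Pi3K92E (-2.10 ± 0.62). In the same libraries the neuroblast genes wor, at 39.3 reads and listed at 0 in control, and ase (19.7 against 2.5 reads) were higher, and the list had camera adjusted p = 0.0179, adjusted p = 0.394 with an estimated correlation. Libraries labelled E75 RNAi had wor at 17 reads and ase at 21 at that stage.

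A hypothesis was that the perturbed γ neurons at 6 h keep a larval rather than an adult profile. Across 7862 genes, which are not independent replicates, the effect of EcR-DN at 6 h correlated with the third instar minus 6 h difference at r = 0.558 and with adult minus 6 h at 0.492, a difference of 0.0660 (0.0419 to 0.0730 leaving out single libraries). For libraries labelled E75 RNAi the difference was 0.0638 (0.0435 to 0.0718) and for Sox14 RNAi 0.0303 (0.0160 to 0.0366), and each kept its sign whichever library was left out. The differences are small, and the third instar had the highest r among the stages for EcR-DN alone. For libraries labelled E75 RNAi 0 h had a higher r, 0.295 against 0.217, and for Sox14 RNAi later pupal stages had higher values than the third instar, such as 0.287 at 15 h against 0.265, so the hypothesis may hold for EcR-DN and is weak for the others.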
